A study of Arabidopsis thaliana with 16 samples.

How the data were processed

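Gene expression was measured in single cells of *Arabidopsis thaliana* callus, the unorganised tissue that forms from explants in culture, by Quartz-Seq2, a plate-based method that counts transcripts by their molecular identifiers (UMIs). Callus came from hypocotyls and was sampled after 7 days on SIM, the second medium of the culture. Wild type was compared with wox13-2, a mutant of the homeobox gene WOX13. The labels describe 2 biological replicates for each of the 2 genotypes, each a separate cell suspension spread over 4 plates of 384 wells. Replicate 1 was collected with a CellenOne dispenser and replicate 2 with a BD FACS Aria II sorter, per the labels' protocols, so replicate, instrument and day cannot be told apart. Plates of one suspension are technical repeats, and the suspension was the unit of replication.

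The authors deposited raw UMI counts per gene and well for all 384 wells of each of the 16 plates. The submitters' processing notes name bcl2fastq 2.17.1.14. A deposited table of the same counts over all cells held equal values and was not used. The aligner, the counting program and the genome build are not given in the sources used here. The authors' cell table, per the file headers, gives the cells they kept with their UMI and gene counts, the percent of mitochondrial and chloroplast UMIs and a cluster number. The filters behind it are not stated, and doublet removal is not stated either. All 3987 cells in that table had UMI and gene counts equal to those of the plate files. The lowest number of detected features in a kept cell was 2007, and 0 wells with more than 2000 features had been left out. Well sheets deposited by the authors give the collection time, an image-based diameter and image intensity for CellenOne wells, and the intensity of forward scatter for sorted wells. The instrument settings are not stated, and the image intensity was not used here. No doublet caller was run, since single cells had been placed in wells. 44 columns of the cell table were not used.

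The files name 29068 genes, of which 28896 matched a locus of the TAIR10.1 reference annotation, and the 48 spike-in entries were left out of library sizes and tests. All coordinates are from that annotation, which may differ from the build the authors used. UMIs of the kept cells were summed per suspension (4 sums), per plate (16 sums) or per cluster and suspension. Levels are given as CPM, computed from these sums, and fold changes are wox13-2 over wild type. The 4 suspension sums held between 22537015 and 85313303 UMIs, and plates between 3648066 and 26217283. Counting error at these depths is small for abundant genes. For a gene with few UMIs in one genotype the ratio of CPM is given with its exact 95% interval, which covers counting error only.

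The test for changed genes was edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, glmQLFit and glmQLFTest, terms for replicate and genotype), with Benjamini-Hochberg adjustment at 0.05. The replicate term was included because the labels tie each replicate to its own instrument and date, with both genotypes in each. Across genes, the replicate difference in wild type correlated with that in wox13-2 (Pearson r = 0.338, genes not being independent). This fit leaves 1 residual degree of freedom per gene, and edgeR's prior contributed 2.42. The same fit was applied within each of the authors' clusters with at least 20 cells in every sum, 10 of 19 clusters. A genotype by replicate interaction was fitted on 16 plate sums and measures the spread between plates only.

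Gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) when at least 3 members were measured, with Benjamini-Hochberg adjustment over the 19 lists tested. The 20 lists covered shoot meristem and boundary regulators, leaf primordium and organ polarity, root tip and lateral root founder, epidermis, stomatal lineage, procambium and cambium, xylem, phloem, endodermis and suberin, root cap, root hair, photosynthetic mesophyll, S phase, G2 and M phase, expansins, xyloglucan endotransglucosylases, auxin, cytokinin, wounding and protoplasting stress, and wound-induced reprogramming. The root cap list had fewer than 3 measured members and was not tested. Members whose locus code carried another symbol in the reference, or was not among the genes measured, were left out. Counts of members were also adjusted over the list alone. Fits with an estimated correlation and with fry were alternatives.

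A cluster was given a tissue name with "-like" when at least 3 markers of one list led it in both replicates and its own leading genes did not go against the name. Cluster sizes were tested with edgeR on cell numbers. A size was compared between genotypes only if none of the cluster's 20 defining genes differed between genotypes by more than 1 on the log2 scale in the same direction in both replicates, with at least 5 cells in every sum. This left 7 clusters. That strict reading of the rule was settled after the size tests had been seen. As an alternative the cells were clustered again (Leiden, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, resolution 1), with all genes and without 1580 genes that differed between genotypes.

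WOX13 across clusters and its co-detection with shoot regulators are values only. For co-detection, cells were thinned to 10000 UMIs, which left out 176 wild-type cells. The Mantel-Haenszel odds ratio over plates was given where at least 20 cells had a UMI of the second gene. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and DESeq2 1.42.0 served as an alternative.

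The rule for naming genes took WOX13, the 10 highest and 10 lowest fold changes past the threshold or, where none passed, the 5 genes with the smallest p in each direction, with a mean of at least 5 CPM and the same direction in both replicates. It also took up to 4 members per list by p, any member of the shoot meristem list, and the 3 highest and 3 lowest genes per cluster. The lists, this rule, the tests and most alternatives were fixed before the data were examined. Alternatives covered normalisation, tool, low-count filter, replicate term, plates as libraries, all wells with at least 1000 UMIs, thinning, pairs of plates, an exchange of genotypes in replicate 2 and each replicate left out. Alternatives added after seeing the data left out the plate with the fewest cells or organelle genes, added the collection hour, tested the lists with thinned cells, used edgeR without its legacy dispersion step, or clustered without genotype-dependent genes.

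The procedures were also tested on simulated counts, a step written after the first fits of the real data. In the whole-callus simulation with one dispersion for all genes, edgeR recovered 43 of 100 genes changed 2-fold and 100 of 100 changed 4-fold among 21998 genes. With dispersions spread over genes, it recovered 0 of 100 and 0 of 100 among 21904 genes. DESeq2 then recovered 8 and 83 among 28087, with 292 false calls, 76.2% of all its calls. Plates as libraries recovered 100 of 100 at both sizes among 19038 genes, with no spread between suspensions simulated. The interaction recovered 33 and 99 of 100 among 19045 genes. Within cluster 0 the fit recovered 27 and 93 of 100 among 16419 genes, and within cluster 3 it recovered 69 and 100 among 15535. The plate, interaction and cluster runs gave all genes a single dispersion, and spread dispersions were not tried there. Their recoveries may thus be too high. With the preset correlation camera found 1 of 1 raised list and 0 of 10 unchanged lists, and with an estimated correlation 0 of 1. Simulated genes varied independently, so this does not show how the preset value acts on lists whose genes vary together. Over 19 simulated clusters, 49 of 100 changed 3-fold were recovered, with 13 calls among 850 others.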

Results

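The data comprise 3987 cells kept by the authors out of 6144 wells. Wild-type callus gave 438 cells with 22537015 UMIs in replicate 1 and 1460 cells with 85313303 UMIs in replicate 2. The wox13-2 callus gave 700 cells with 34970441 UMIs and 1389 cells with 78391604 UMIs. Median UMIs per cell were 36326 and 41636.5 in wild type and 33667.5 and 40363 in wox13-2, and median genes per cell were 8253.5 and 8743.5 against 8045 and 8817. Mitochondrial UMIs made up 0.0888% and 0.0958% of the wild-type sums and 0.06002% and 0.0467% of the wox13-2 sums. Plates of wox13-2 were collected 2.32 hours later in the day than wild-type plates in replicate 1 and 2.07 hours later in replicate 2. The genotypes did not overlap in hour. The last wild-type plate was at 14.8 hours against 15.5 for the first wox13-2 plate in replicate 1, and 14.7 against 15.7 in replicate 2. Fits with the collection hour, run on the 16 plates, thus extend a slope within suspensions across that gap. A value that turns with the hour does not settle its direction.

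WOX13 (AT4G35550, chromosome 4, 16875521 to 16877451, TAIR10.1), which encodes a homeobox transcription factor, is the gene named in the mutant genotype, so its level was read first. Wild-type suspensions held 72.4 and 78.1 CPM (75.3 ± 4.09, SD, n = 2) and wox13-2 suspensions 3.37 and 2.47 CPM (2.92 ± 0.636, SD, n = 2). The log2 fold change was -4.77 (SE 0.19), with an edgeR adjusted p of 0.0592 over all genes. The lower WOX13 level follows the titles and genotype labels in both replicates, whereas the description field of the sorted samples carries the other genotype's code. The position of the wox13-2 lesion is not given in the sources used here, and a count of transcript ends does not show whether a functional transcript was made.

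**Figure D1:**
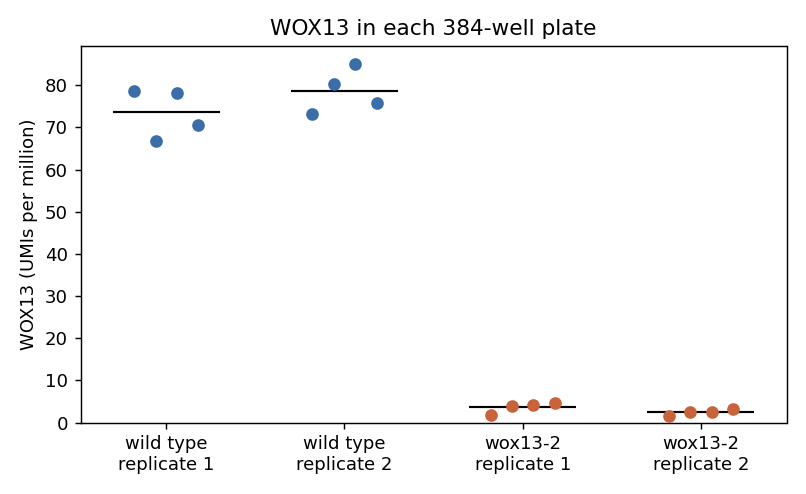
WOX13 level (CPM, vertical axis) in each of the 16 plates, grouped by genotype and replicate, with 1 point per 384-well plate and a line at the mean of the 4 plates. Every wild-type plate lay above every wox13-2 plate, and the summed suspensions held 72.4 and 78.1 against 3.37 and 2.47 CPM.

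The whole-callus comparison asks which genes differ when WOX13 is reduced. The 5 genes higher in wox13-2 with the smallest p included epidermal genes. PDF2, a homeodomain protein of epidermal identity, was at 38.5 and 24.8 CPM against 1.91 and 1.31 (log2 4.22, SE 0.13). DCR, an acyltransferase required for cutin, was at 91.3 and 66.4 against 7.32 and 4.86 (log2 3.65, SE 0.10). ARD3, an acireductone dioxygenase, AT5G22580 and ELP had log2 fold changes of 4.56, 4.13 and 6.99. The 5 lower genes were AT4G38932 (-8.13), AT2G01090 (-7.48, 11 UMIs in wox13-2, ratio 0.00575, 95% interval 0.00286 to 0.0103), AT5G38000 (-3.69), AT5G23830 (-3.19) and LSU1 (-2.52), a gene induced by sulphur shortage.

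None of these genes passed the threshold. The edgeR test called 0 of 21831 genes at an adjusted p under 0.05, with a smallest adjusted p of 0.0513, while 4089 genes had an unadjusted p under 0.05, 2071 higher and 2018 lower. The DESeq2 Wald test called 1596 genes, 923 higher and 673 lower, and limma voom on the 16 plates called 5436. Without the low-count filter edgeR called 386, and without the wild-type plate that held 57 cells it called 201, a setting chosen after seeing the data. Of the genes tested, 1489 differed by more than 2-fold in the same direction in both replicates, 1072 higher and 417 lower. Across genes, the genotype differences of the replicates correlated with a Pearson r of 0.571, genes not being independent.

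Markers of the epidermis had the smallest camera p of the gene lists in whole callus. All 11 measured members were higher with the test adjusted over the list alone, and 0 passed over all genes (edgeR). The median log2 fold change was 2.87. ATML1, the close relative of PDF2, was at 33.7 and 22.6 CPM against 2.40 and 1.34 (log2 3.90), and LACS2, an acyl-CoA synthetase of cutin synthesis, had a log2 fold change of 2.87. camera gave the list an adjusted p of 5.76e-14. The call was lost with an estimated correlation, which rested on 1 residual degree of freedom (adjusted p = 0.722 with an estimated correlation, the same value for every list).

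Genes of leaf primordia and organ polarity were also higher as a group, with 11 of 13 members above 0, 6 of them higher when adjusted over the list alone (median log2 2.75, camera adjusted p = 7.51e-05). The size was less certain than the direction, with medians of 0.996 and 3.25 in the replicates and of 0.82 with thinned cells. The call was lost as above (adjusted p = 0.722 with an estimated correlation) and with the collection hour added to a fit on the 16 plates (camera adjusted p = 0.0693). PRS, a homeobox gene of leaf margins, had 321 UMIs in wox13-2 against 4 in wild type (ratio of CPM 76.3, 95% interval 29.5 to 282). AS2, a regulator of leaf polarity, had 531 against 13 (ratio 38.9, interval 22.5 to 73.5). Photosynthetic mesophyll genes were above 0 in 23 of 23 members in the fit over both replicates, 2 of them higher over the list alone (median log2 0.50, camera adjusted p = 2.75e-04, adjusted p = 0.722 with an estimated correlation). Replicate 2 gave most of this, with a median of 1.16 against -0.058 in replicate 1, where 14 members lay below 0. RBCS2B, a small subunit of Rubisco, had 254 UMIs against 11 (ratio 22.0, interval 12.1 to 44.6), and GLK2, a regulator of chloroplast development, had a log2 fold change of 1.76 (1.13 and 2.31 in the replicates) without passing over the list alone (edgeR adjusted p = 0.0844).

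The S-phase list, with 16 of 17 members above 0, and the G2 and M phase list, with 18 of 22, were shifted by small amounts. Their medians were 0.26 and 0.12, and no member of either passed over the list alone (edgeR), with 2 and 4 members at an unadjusted p under 0.05. camera adjusted p-values were 0.00258 and 0.0281 (adjusted p = 0.722 with an estimated correlation for both). PCNA1 and PCNA2, the DNA clamp of replication forks, had log2 fold changes of 0.49 and 0.39, and the B-type cyclins CYCB1;1 and CYCB2;3 of 0.49 and 0.37. With thinned cells CYCB1;1 in wox13-2 turned to -0.025 and CYCB2;3 to -0.19, and with the collection hour CYCB1;1 in wox13-2 turned to -0.11. The G2 and M phase list as a whole turned to a median of -0.028 with thinned cells and -0.29 with the collection hour, and 14 of its members lay below 0 in replicate 1, so its direction is not settled. Without the replicate term it no longer passed (camera adjusted p = 0.0579). The S-phase list kept its direction and its call with thinned cells and with the collection hour (medians 0.27 and 0.65), but replicate 2 gave most of it, with a median of 0.46 against 0.028 in replicate 1, where 6 members lay below 0.

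Expansins, proteins that loosen cell walls, included members in both directions. Adjusted over the list alone, 7 were lower and 2 higher, the median being -0.50 and the mean 0.12 (camera adjusted p = 0.0579). EXPA17 was at 3.35 and 1.36 CPM against 49.8 and 14.5 (log2 -3.71), EXPB3 at 471 and 472 against 972 and 958 (log2 -1.09), and EXPA4 had a log2 fold change of -0.71. EXPA5 had 171 UMIs in wox13-2 against 3 in wild type (ratio 54.2, interval 18.25 to 266). Of the xyloglucan endotransglucosylases, enzymes that rejoin wall polymers, 7 were lower and 4 higher over the list alone (camera adjusted p = 0.116), among them XTH4 (-0.76) and XTH22 (0.82, but -0.073 with the collection hour).

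Among auxin genes 4 were lower and 3 higher over the list alone, the median being -0.19, the mean 0.00 and the camera adjusted p 0.2004. IAA2, an Aux/IAA repressor, and PIN7, an auxin efflux carrier, were lower (-0.64 and -1.03), and GH3.2, an auxin-conjugating enzyme, was at 0.73, but at -0.58 with the collection hour. No cytokinin gene passed over the list alone by edgeR, 3 being higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.428), with CRF2 at 0.48 and ARR6 at -0.40. Of the phloem genes 2 were lower, the sucrose transporter gene SUC2 (-0.71) and OPS (-0.54), with a camera adjusted p of 0.0711, which passed with thinned cells (6.48e-05). No procambium gene passed over the list alone by edgeR, with 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0715, and 0.00809 with the collection hour), WOX4 being at -0.43 and MOL1 at -0.51. No xylem gene did either, with 1 lower at an unadjusted p under 0.05, VND7 at -0.71 (camera adjusted p = 0.229). The median of the xylem list was 0.55, with 11 of 15 members above 0, but the replicates went opposite ways. Replicate 1 had a median of -0.66 with 13 members below 0, and replicate 2 a median of 2.35 with 2 below 0. The endodermis list had 1 member higher, FAR1 (2.93), a fatty acyl reductase of suberin (camera adjusted p = 0.167).

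In the stomatal lineage list (camera adjusted p = 0.185) 2 members were higher over the list alone and 1 lower. SPCH, which starts the lineage, had 459 UMIs against 11 (ratio 39.7, interval 22.0 to 80.1), while POLAR was at 4.75 and 5.86 CPM against 8.61 and 12.2. The root hair list had a camera adjusted p of 0.20005. Its 2 higher members were GL2 (116 UMIs against 9, ratio 12.3, interval 6.24 to 27.5) and WER (log2 3.05). RHD6 was lower (-1.37) without passing over the list alone (edgeR adjusted p = 0.0624). Members were not sorted by their role, so the direction of this list does not stand for more or fewer root hairs. Root tip genes had 2 higher and 1 lower (camera adjusted p = 0.218), SCR having a log2 fold change of 1.49 and WOX5 of 2.15. The wounding and protoplasting stress list had 2 higher and 2 lower (camera adjusted p = 0.2004), with WRKY40 at 1.12 (-0.74 with the collection hour) and VSP2, a jasmonate-responsive gene, at -3.16. No wound-induced reprogramming gene passed over the list alone by edgeR, with 1 at an unadjusted p under 0.05, WIND2 at -0.31 (camera adjusted p = 0.428). Over the plates of a suspension, the slope of the stress list was 0.57 (SE 0.067, log2) per hour of collection. Times the gap in hours between genotypes this gives 1.25 (SE 0.15), against an observed difference of 0.11.

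Of the shoot meristem and boundary regulators, 2 were higher and 1 lower over the list alone (camera adjusted p = 0.2004). CLV3, a peptide gene of shoot stem cells, was at 16.7 and 6.03 CPM against 7.90 and 2.41, but turned to a log2 fold change of -0.91 with the collection hour and -0.93 on plates 1 and 2. PLT3 had a log2 fold change of -0.49, and HEC2 had 90 UMIs against 10 (ratio 8.56, interval 4.45 to 18.5). WUS, which maintains shoot stem cells, was at 2.57 and 5.46 CPM against 11.8 and 2.74, so the replicates went opposite ways (-2.25 and 0.94). CUC1 did so too (-0.86 and 0.51), while CUC2, a boundary gene like CUC1, was at -0.29 in both, but at 0.014 with thinned cells and 0.16 with the collection hour. CUC3, STM and ESR2 had log2 fold changes of 2.05, 1.30 and 2.41, none past over the list alone (edgeR), and replicate 2 gave more of it (2.88, 2.34 and 4.27 against 1.198, 0.22 and 0.54).

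**Figure D2:**
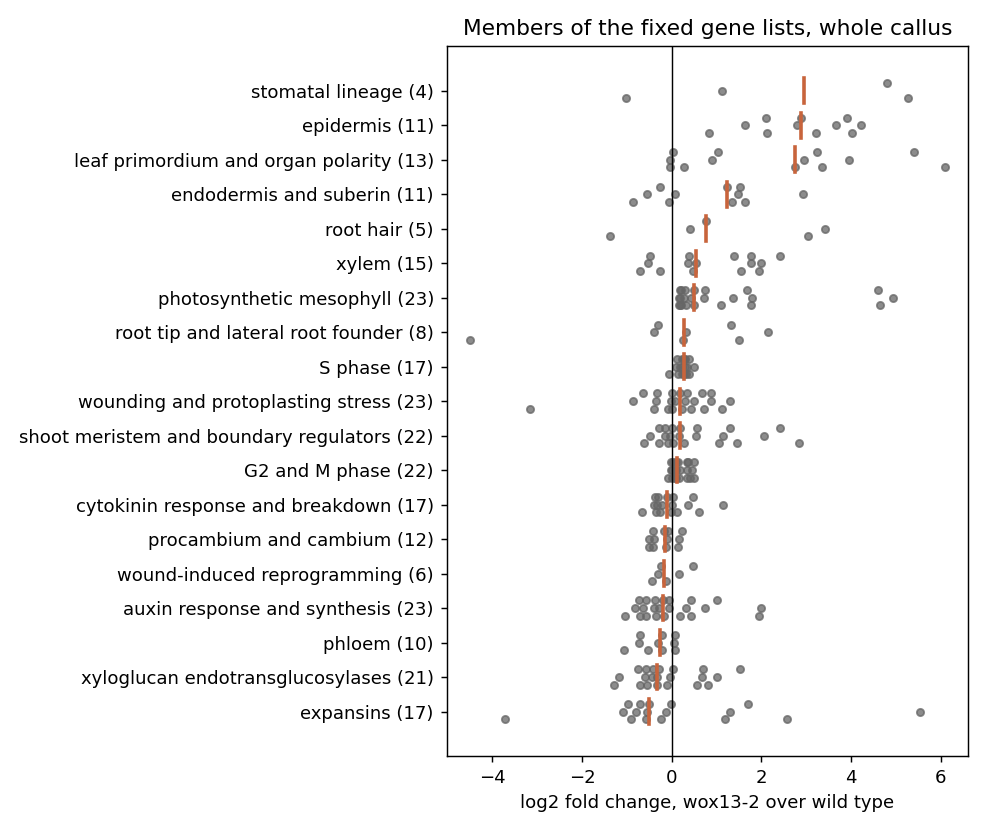
Log2 fold changes (wox13-2 over wild type, horizontal axis) of the measured members of each gene list, 1 point per gene, with the list median as a vertical bar and the number of members in parentheses. The 11 epidermis members all lie above 0, with a median of 2.87, and expansins spread to both sides around a median of -0.50.

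The comparison within clusters asks which genes differ among cells of one kind. In the 10 clusters tested, 1283 pairs of gene and cluster passed, 727 higher and 556 lower, in 815 genes. Of the genes, 108 passed in 3 or more clusters, 50 of them higher each time and 56 lower each time. UGT73B3, a glycosyltransferase gene, fell in 8 of 10 clusters, AT4G38932, AT4G33930 and AT4G39955 in 7, and WOX13 in 7. AT5G38900 rose in 7 of 9 clusters, ARD3 in 5 of 6 and LBD41 in 5 of 10, all chosen after their values were seen. UGT73B3, AT4G38932, AT4G33930 and AT4G39955 lie on chromosome 4 with WOX13. For them, an effect of WOX13 cannot be told apart from a stretch of another strain's chromosome carried with the allele. In clusters 1, 11 and 13 WOX13 was also lower, without passing (log2 -4.43, -5.11 and -4.90, edgeR adjusted p = 0.0631, 0.141 and 0.368). In cluster 8, ARD3 rose from 0.607 and 0.828 CPM to 62.6 and 41.9, and WRKY51 from 1.21 and 0.710 to 14.1 and 11.4, while AT4G39320 fell from 609 and 525 to 10.2 and 6.28. SOT12 rose in cluster 0 (log2 4.88), FTM1 in cluster 1 (4.28) and PNP-A in cluster 4 (4.67). In cluster 1, UGT73B3 (-5.18) and AT1G03820 (-4.33) fell. In the S-phase-like cluster 3, ARD3 rose (log2 4.96) and AT4G33930 fell (-6.02).

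Expansins fell in 8 pairs of gene and cluster and rose in 1 (the list members named here were chosen after their values were seen). EXPA15 fell in clusters 3, 4 and 8 (log2 -0.85, -1.80 and -1.39), EXPA8 in clusters 2, 3 and 4, EXPA17 in cluster 12 (-2.45) and EXLA2 in cluster 3, while EXPA3 rose in cluster 7 (1.71). GH3.2 rose in clusters 3, 4, 7 and 8 (1.02, 1.92, 0.93 and 3.14), and IAA20, IAA30 and PIN7 fell in cluster 7, which gave 4 auxin pairs higher and 3 lower. Stress genes rose in 5 pairs and fell in 1. WRKY40 rose in clusters 3 and 7, CBF2 in 3, CML12 in 7 and ERF5 in 8, and VSP2 fell in 12. Xyloglucan endotransglucosylases rose in 3 pairs, XTH24 in cluster 3 and XTH22 in clusters 7 and 12, and fell in 1. CKX6 and CKX1, cytokinin oxidase genes, rose in clusters 7 and 12. STM rose in cluster 3 from 0.951 and 0.694 CPM to 15.0 and 6.83 (log2 3.51), as did ACL5 (1.04) and TMO5 (1.06) there.

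LTP1, a lipid transfer protein gene, was the only epidermis member past the test within a cluster, and it fell in cluster 4 (log2 -2.23). The epidermis-like cluster 9, with 9 and 12 wild-type cells, was too small for this test. Changes within epidermis-like cells were thus not examined. The S phase, G2 and M phase, leaf primordium, photosynthetic, phloem, endodermis, root hair, root tip, stomatal and wound-induced reprogramming lists had 0 of 612 pairs past by edgeR, the tool run within clusters, with 152 at an unadjusted p under 0.05. The G2/M-like cluster 11 and the procambium-like cluster 13 had 0 genes past by edgeR, with 1010 and 808 at an unadjusted p under 0.05. WOX13 itself did not pass there (log2 -5.11 and -4.90), so a count of 0 does not show that no gene changed. Without the replicate term edgeR called 5 in cluster 11, all lower, and 0 in cluster 13, with 875 at an unadjusted p under 0.05. AT4G23670 (-2.74) and WRKY70 (1.96) in cluster 11, and CML12 (2.63) and WRKY70 (2.59) in cluster 13, were among the smallest p there without passing. Without the replicate term 274 pairs passed in place of 1283, and 34 of the 41 pairs named here with a cluster that had passed did not pass then.

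Cluster sizes were compared for 7 of 19 clusters, with p adjusted over all clusters of a clustering. Of the 12 not compared, clusters 1, 6, 9, 10 and 16 held larger shares in wox13-2 in both replicates. Clusters 8, 12 and 18 held smaller ones, and the rest were mixed. Cluster 6 held 1.60% and 3.22% of wild-type cells against 7.29% and 10.9% (values with no test). The compared clusters thus do not give the whole change in composition. Cluster 5, defined by genes including the glucosinolate enzymes CYP79B2 and CYP79B3, held 6.16% and 12.1% of wild-type cells and 2.57% and 3.096% of wox13-2 cells, a lower share in both replicates (log2 -1.66, edgeR adjusted p = 0.0122). The S-phase-like cluster 3 held 9.82% and 6.92% against 5.71% and 6.77%, and did not pass by edgeR. Nor did the G2/M-like clusters 11, 14 and 15. By an exact permutation of plates within replicates, which takes plates as units, clusters 4 and 15 passed beside cluster 5, both lower (adjusted p = 0.0252 and 0.0494). In the new clustering with all genes edgeR called 1 of 6 comparable clusters, the one that held 98.1% of cluster 5 (log2 -1.75, edgeR adjusted p = 0.00314). The size of the epidermis-like cluster 9 was not compared because 2 of its 20 defining genes differed between genotypes. In the clustering without genotype-dependent genes, the epidermis-like cluster held 1.83% and 0.890% against 10.6% and 8.57%. It too had 2 of 20 defining genes that differed, neither used in that clustering, so these are values with no test. In that clustering edgeR called 0 of 7 comparable clusters, with 0 at an unadjusted p under 0.05, and an exact permutation of plates within replicates called 0, with 3 at an unadjusted p under 0.05. The cluster that held 90.9% of cluster 5 was not among them because 4 of its defining genes differed, and it held 14.2% and 17.5% of wild-type cells against 7.86% and 5.54%.

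**Figure D3:**
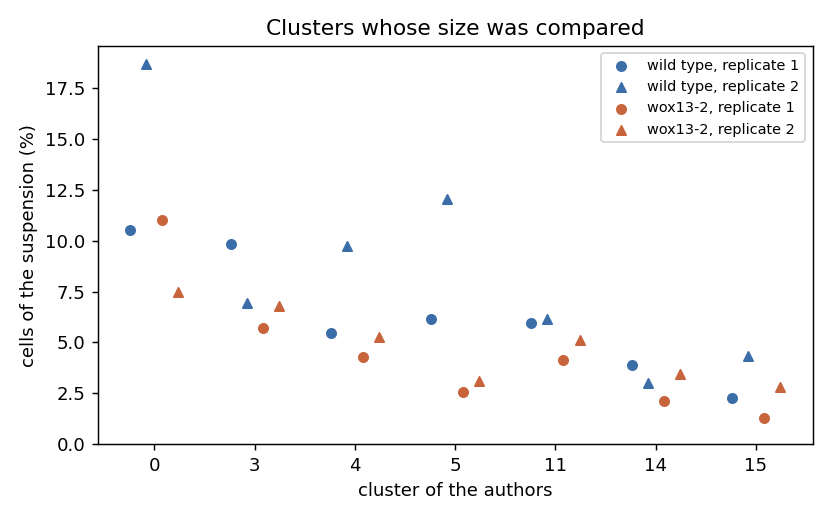
Percent of cells of each suspension (vertical axis) in the 7 of the authors' clusters whose size was compared (horizontal axis), by genotype (colour) and replicate (symbol). Cluster 5 held 6.16% and 12.1% of wild-type cells and 2.57% and 3.096% of wox13-2 cells.

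The genotype effect differed between the replicates for 250 genes in the interaction test on plates (edgeR), 195 with a higher log2 fold change in replicate 2 and 55 with a lower one. Photosynthetic genes made up 9 of the former. The test used sums over all cells, and CAB1, LHCB6, YAB3 and CLV1 were among the markers that led cluster 1. That cluster held 5.25% of wild-type and 6.86% of wox13-2 cells in replicate 1, and 1.92% and 14.8% in replicate 2 (values with no test). A change of shares and a change within cells cannot be told apart here. For CAB1, a light-harvesting gene, the log2 fold change was 0.05 in replicate 1 and 1.39 in replicate 2. It was -0.21 and 0.81 for LHCB6, and -0.32 and 0.74 for RBCS1A. LHCA1, LHCA3, LHCB3, LHCB5, PSAF and PSBO1 were the others. The cytokinin genes ARR15, ARR16 and CKX5 were also higher in replicate 2, with YAB3 of the leaf primordium list and CLV1 of the shoot meristem list, and IAA19 was lower. Without the low-count filter 91 genes passed, and 9 of the 15 list members named here no longer did. The replicate term of the whole-callus fit, which joins instrument and day, called 0 genes (edgeR), with 1780 at an unadjusted p under 0.05.

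WOX13 was measured in most clusters of wild-type callus, highest in the G2/M-like cluster 14 at 314 and 294 CPM (304 ± 13.9, SD, n = 2), followed by the G2/M-like cluster 15 at 115 and 182. The G2/M-like cluster 11 held 54.2 and 56.8, and the S-phase-like cluster 3 held 69.9 and 69.9. Cluster 16, led by 22 G2 and M phase markers and 4 shoot meristem markers, held 61.7 and 7.25, from 5 and 3 UMIs in 2 and 3 cells. The epidermis-like cluster 9 held 27.9 and 15.3 CPM, from 15 and 10 UMIs in 9 and 12 cells. In the whole wild-type suspensions WOX13 was at 72.4 and 78.1 CPM. These values were not tested.

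In thinned wild-type cells, the odds ratio of detecting CUC1 given a WOX13 UMI was 0.824 and 0.839 in the replicates (0.831 ± 0.0105, SD, n = 2), and that of CUC2 was 1.63 and 0.737 (1.18 ± 0.630, SD, n = 2). In unthinned cells the ratios were 1.54 and 1.61 for CUC1, and 3.73 and 2.16 for CUC2. In replicate 2, the only one with enough positive cells, the ratios were 0.439 for STM, 0.670 for ESR1 and 0.496 for LAS. Too few cells had a UMI of WUS or ESR2. Cells are not replicates, so no test was made.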

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

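The tests given here were chosen after the results they bear on had been seen, except those of tandem gene copies and of depth. In wild-type replicate 2, plate 2 stood apart from the other plates of its suspension with a median of 6636 genes per cell against 9398.5 (a gap of 0.862 of the range). It was the only such case in 28 tests, which applied several measures to the plates of the 4 suspensions. Chance gives about 1 case in 20 tests, so 1 case in 28 is no more than chance gives.

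For 250 genes the genotype effect differed between the replicates (edgeR interaction on plates). Over 30 splits of the plates, the real one included, 1 gave as many genes, and the highest other gave 12. Plates are technical repeats, so any difference between suspensions would give this. The splits cannot exclude chance between suspensions. With plates as libraries 5536 genes differed between genotypes, and 1 of 30 splits within replicates gave as many, the highest other being 2095. For the same reason these splits cannot exclude chance between suspensions either.

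Of 10 genes nearly absent in wox13-2, 6 lay on chromosome 4 with WOX13 (AT4G22230, AT4G33930, UGT73B3, AT4G38932, SEC14 and AT4G39320), against 15.2% of all genes at that level (exact one-sided hypergeometric test, p = 0.00148, on genes picked after the pattern was seen). Of 24 genes nearly absent in wild type, 3 did, against 15.01% (exact one-sided hypergeometric test, p = 0.721). Of the 6 genes, AT4G22230 started at 11762233. The others started between 16264269 (AT4G33930) and 18288770 (AT4G39320), with WOX13 at 16875521. Of the rest of the 10, AT2G01090 and MLP329 started at 79779 and 239669 on chromosome 2. PME2 and AT5G05840 lay on chromosomes 1 and 5. Carry-over of wild-type reads into wox13-2 wells is argued against, since 5 of the 10 genes kept a smaller share of their wild-type CPM than the 3.58% of WOX13 (95% interval 3.18 to 4.01). All genes called within any cluster, higher or lower, were pooled in a count of crowding. At most 21 lay in 200 neighbours, against a 95th percentile of 22 in shuffled orders, and 8 lay around WOX13. Such a pooled count can miss a stretch that holds a few strongly lowered genes. With neighbouring genes counted once the values were 15 and 15, so tandem copies cannot be told apart from no crowding. A stretch of another strain's chromosome carried with the allele may still account for the nearly absent genes on chromosome 4, as may an effect of WOX13 on them, which was not tested.

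The epidermis-like cluster of the clustering without genotype-dependent genes held 1.83% and 0.890% of wild-type cells and 10.6% and 8.57% of wox13-2 cells, values with no test since 2 of its 20 defining genes differed between genotypes. Clusters drawn by genotype-dependent genes are argued against, since the smaller log2 ratio of the replicates was 2.53 when those genes, the 2 included, were left out of the clustering. Depth is argued against too, since among cells thinned to 10000 UMIs those with at least 3 epidermis markers made up 5.48% and 3.83% against 14.7% and 12.5%, the smaller log2 ratio being 1.43. If the slope within suspensions holds across the gap between genotypes, a trend with the collection hour is argued against as the whole cause. The epidermis list differed by 3.55 (SE 1.09, over plates) with that slope taken out. With the hour in the fit its median was 3.33, with 11 of 11 members above 0 (camera adjusted p = 5.29e-05), while the median of the stress list turned to -0.92. A longer time in suspension as part of the cause cannot be told apart, since the slope times the gap gave -0.32 (SE 0.99) against a difference of 3.23, and the hour at which each suspension was made is not given. A larger share of epidermal cells in wox13-2 callus thus stays open as a hypothesis, with 2 suspensions per genotype.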

How the results depend on the processing

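The settings that added the collection hour, tested the lists with thinned cells, left out the plate with the fewest cells or organelle genes, dropped edgeR's legacy dispersion step or clustered without genotype-dependent genes were chosen after seeing the data. The cause was not tested for any value given here. The count of genes changed in whole callus, 0 by edgeR, became 1596 with DESeq2, 386 without the low-count filter and 4 with no replicate block. It was 248 with thinned cells and 201 without the plate with the fewest cells. The count was 5536 with plates as libraries, 5436 with limma voom on plates and 4428 with plates as libraries and the collection hour. It stayed at 0 with size factors, all wells, either pair of plates, the exchange of genotypes, the other dispersion step and without organelle genes. With 1 replicate left out no residual degrees of freedom remained, so those are values with no test. WOX13 kept its direction in all settings but the exchange, and passed with DESeq2 (-4.76), without the filter (-4.75), with plates (-4.76), with voom (-4.88), thinned (-4.79), without the plate (-4.76) and with the hour (-5.57). Without each replicate it lay between -5.01 and -4.47. Of the lists, 5 passed, and 0 did with an estimated correlation, 0 with fry and 8 on plates 3 and 4, which added expansins, xyloglucan endotransglucosylases and the shoot meristem list, and where the xylem list turned lower without passing (median log2 -0.45, camera adjusted p = 0.129). On plates 1 and 2 the G2 and M phase list no longer passed (0.131) and the stress list did (0.0473), and without the plate with the fewest cells the phloem list did (0.0327). With thinned cells 5 passed too, the phloem list among them (6.48e-05), and the G2 and M phase list turned lower (camera adjusted p = 0.475) and the cytokinin list higher (0.391). On the 16 plates with the collection hour added 5 passed, the procambium list among them (0.00809) and the leaf primordium list, with 8 members measured, not (0.0693). There the G2 and M phase (0.676), endodermis (0.822), xylem (0.657) and stress (8.78e-07) lists turned lower and the cytokinin list higher (0.763). The lists were not tested on plates without the hour, so these changes cannot be put down to the hour alone. Of the compared clusters, 1 passed, 3 did by permutation of plates, 1 in the new clustering with all genes and 0 without genotype-dependent genes, where the counterpart of cluster 5 was not compared. The log2 ratio of cluster 5 lay between -1.93 and -1.23 without each replicate. The log2 ratio of the epidermis-like share, 2.93, lay between 2.47 and 3.13 without each replicate. Within clusters, 1283 pairs became 127 with at least 50 cells, where 1 cluster was left, and 274 with no replicate block. The interaction count, 250, became 91 without the filter. WOX13 in cluster 14 lay between 294 and 314 CPM by replicate. The co-detection ratio of WOX13 and CUC1 was 1.58 unthinned and 0.824 to 0.839 by replicate, and that of WOX13 and CUC2 was 2.95 unthinned and 0.737 to 1.63.

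Of the values of the 63 genes named besides WOX13 over 15 settings, 60 were reversed, 615 kept direction and side of the threshold, and 242 newly passed. The exchange of genotypes in replicate 2 gave 45 of the 60 reversals. With each replicate left out, 3 more values were reversed, and 9 without replicate 1 and 11 without replicate 2 moved by more than the spread between replicates. With the collection hour, CYCB1;1 turned to -0.11, GH3.2 to -0.58, XTH22 to -0.073, WRKY40 to -0.74, CLV3 to -0.91, CUC1 to 1.34, CUC2 to 0.16 and WUS to 0.92. With voom CUC1 turned to 0.25. With thinned cells CYCB1;1 in wox13-2 turned to -0.025, CYCB2;3 to -0.19, CUC1 to 0.25, CUC2 to 0.014 and SUS1 to 0.044. On plates 1 and 2 CLV3 turned to -0.93. Without each replicate CUC1 lay between -0.86 and 0.51, WUS between -2.25 and 0.94 and SUS1 between -0.61 and 0.14.

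The exchange of genotypes in replicate 2 averages opposite effects. It left WOX13 at 0.30, ARD3 at -0.22, AT5G22580 at -0.00015, DCR at -0.095, ELP at -0.99 and PDF2 at -0.025. AT4G38932 was at 0.42, AT5G38000 at 0.12, AT2G01090 at 0.24, LSU1 at 0.051, ATML1 at -0.18, LACS2 at -0.13, PRS at -0.52, SPCH at -0.0069, POLAR at 0.10, RBCS2B at -1.02 and GLK2 at -0.61. CYCB1;1 in wox13-2 was at -0.0027, CYCB2;3 at -0.14, PCNA1 at -0.21, PCNA2 at -0.12, IAA2 at 0.068, PIN7 at 0.26, CRF2 at -0.00082 and EXPA5 at -0.64. SUC2 was at 0.15, OPS at 0.086, FAR1 at -0.25, SCR at -0.19, GL2 at -0.082, VSP2 at 0.49, WIND2 at 0.00065 and VND7 at 0.089. CLV3 was at -0.13, HEC2 at -0.27, CUC2 at 0.0024, CUC3 at -0.85, STM at -1.07 and ESR2 at -1.87. AT4G33930 was at 0.45, UGT73B3 at 0.32, AT4G39320 at 0.49, AT4G22230 at 0.77, SEC14 at 0.66, PCO1 at -0.050 and SUS1 at 0.38.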

Other observations

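The tests of the low-oxygen hypothesis were chosen before their results were seen, although 12 of its 39 genes had been seen in the data by then. The medians and counts by replicate, the comparison with the stress list and the tests of the hour as the whole cause were added afterwards. The list held ADH1, an alcohol dehydrogenase of fermentation, PCO1, a plant cysteine oxidase of oxygen sensing, HRA1 and LBD41, regulators induced by low oxygen, and SUS1, a sucrose synthase. In whole callus ADH1 had a log2 fold change of 0.70 in wox13-2, PCO1 of 0.71, HRA1 of 1.52 and SUS1 of -0.24, none past the test (edgeR adjusted p = 0.266, 0.0910, 0.0592 and 0.612). Of all members, 35 of 39 lay above 0 in the fit over both replicates, with a median of 0.88. In replicates 1 and 2, 1 and 10 members lay below 0. Within the S-phase-like cluster 3 and cluster 7 the test called 17 and 14 members higher, 6 and 6 of them not seen before. Of the members not seen before, 1 was called higher in cluster 8 and 1 lower in cluster 4, and edgeR called 0 in the other 6 clusters, with 40 pairs of gene and cluster higher and 3 lower at an unadjusted p under 0.05.

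Cells of wox13-2 had a median image-based diameter of 13.3 against 14.2 in replicate 1, in a unit not given in the file, and a median forward scatter of 60986 against 76516 in replicate 2. These values were not tested. Over the plates of one suspension, 1680 genes varied with the hour of collection (edgeR on 16 plates).

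The hypothesis was that the low-oxygen response was higher across callus cells of wox13-2. The 27 members not seen before had a median of 0.51 in whole callus, 23 of them above 0 in the fit over both replicates. Their medians were 0.62 and 0.30 in replicates 1 and 2, with 1 and 10 of them below 0. In 9 of 10 clusters their median lay above the 95th percentile of 10000 lists matched on expression, the exception being cluster 1 at 0.090 (percentile 87.25). The matched lists hold unrelated genes, so they do not cover genes that vary together, and the 10 clusters come from the same 4 suspensions, so their agreement is not independent. The values are those a higher response would need, and the hypothesis stays open with 2 suspensions per genotype. For the members not seen before, a trend with the collection hour may account for the whole difference, which fell from 0.57 to 0.21 (SE 0.21, over plates) with that slope taken out. For all members 0.93 (SE 0.27) was left, but these include the 12 genes that had been seen, so the trend as the whole cause cannot be told apart. Nor can a longer time in suspension, since the slope times the gap gave 0.18 (SE 0.24) against a difference of 1.11 for all members. The stress list goes against extra time, with 1.25 (SE 0.15) against a difference of 0.11, but it is no part of this pattern, and the hour at which each suspension was made is not given.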
